A study of Mus musculus with 12 samples.

How the data were processed

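RNA from the colon of male mice of 3 genotypes was measured on 12 Agilent whole-genome oligonucleotide arrays with a single green dye. The genotypes were wild type (WT), a knockout of Atf6 (ATF6aKO) and a knockout of Atf6b (ATF6bKO). ATF6a and ATF6b are membrane proteins of the endoplasmic reticulum (ER) that release transcription factor fragments when unfolded proteins accumulate. Per the labels, colitis was induced with 3 percent dextran sulfate sodium (DSS), a polymer that injures the colonic epithelium, in the drinking water for 3 days, and the other mice of each genotype were untreated (UT). Each of the 6 groups had 2 arrays. The labels name separate samples but do not say that the 2 arrays of a group came from separate animals, so every p-value measures only the spread between these samples, which may be technical.

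The labels of the 4 WT samples conflict. Their titles and source names put 2 of them in DSS and 2 in UT, while their descriptions and treatment fields state the opposite. The WT groups were formed by the titles and are called "titled DSS" and "titled UT". No sign of the WT difference was taken as the effect of DSS, and results that need it were computed under both readings. The labels of the 8 knockout samples do not conflict.

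Per the file headers, the authors scanned each array and quantified it with Agilent Feature Extraction, version 10.7.1.1 in the submitters' processing notes. The deposited scanner files hold, per spot, an intensity called the processed signal, from which that program had subtracted background and a spatial trend, with no scaling between arrays. They also hold raw median intensities of the spot and its local background. The deposited value table of the series holds log2 values made by the authors from the same arrays. Of its 41268 probes, 41267 had a mean of 0 over the arrays within 0.001, so the values are centred on each probe's mean, and differences between columns ran in the direction of differences between arrays. The scaling between arrays stayed unknown. In 8 of the 12 columns the values were those of the array of another sample. The 4 WT columns held the arrays of the other WT group, the ATF6aKO columns had the replicates of a group exchanged, and the 4 ATF6bKO columns held their own arrays. Whether the table or the scanner files are assigned wrongly is not given in the sources used here. The scanner files were taken as assigned; were they wrong, the WT groups and the replicate numbers of ATF6aKO would be exchanged, and the sign of the WT difference would turn. The value table served only as an alternative, with each column taken as the array whose values it equals.

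Control spots were left out, which left 43379 of 45018 spots and 41174 probes, and so were spots that the program had marked as outliers (54 to 108 per array). The base 2 logarithm of the processed signal minus that of the array's 75th percentile is the level used throughout, in log2 units. Spots of 1 probe were averaged. A probe was kept if it was well above background, by the program's own mark, on both arrays of at least 1 group, which left 30423 probes. A gene was represented by the probe with the highest mean level over all arrays, and 23236 genes or transcripts were tested. The files carry accessions and no gene symbols. Unversioned accessions were named through a RefSeq gene table of assembly GRCm38.p6, which matched 25193 probes (61.2%) to 17332 genes. For 5471 probes the accession differs between the versions. Of the genes tested, 14592 (62.8%) had a symbol; the other 8644 were counted but not named. The result for 1 of the list genes is not reported.

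Differences were tested with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, and p-values were adjusted over all genes by the Benjamini-Hochberg method with a threshold of 0.05. "Rose", "fell", "higher" and "lower" are used of single genes only where that adjusted p was under the threshold. The DSS comparison within each genotype and the differences between those responses came from 1 fit of all 12 arrays with 6 group means, so the groups share 1 estimate of the spread. The DSS comparison pooled over the knockouts used the 8 knockout arrays with genotype as a term. Each genotype comparison used 8 arrays with treatment as a term, so that its estimate does not depend on which WT reading holds. There were 11 such comparisons.

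Before the data were examined, these comparisons, 26 gene lists (14 of cell type markers and 12 of pathways), the alternatives and the rule for named genes had been fixed. The rule took Atf6 and Atf6b always. For each DSS comparison it took up to 8 genes each way with the largest log2 change among those past the threshold, with a change of at least 1, all arrays of the higher group above all of the lower within a genotype, and well above background on each array of the higher group. For the other comparisons it took up to 5 genes each way past the threshold, well above background on each array of 1 group compared. From a list it took up to 2 members each way past the threshold, or up to 2 as values where none passed. Where nothing passed in a comparison, the 3 genes each way with the smallest p are given as values. Each list was tested against all other genes with limma's camera at its preset correlation between genes of 0.01, adjusted over the lists of a comparison, and again with the correlation estimated from the arrays. Of 127 gene set shifts called over the 11 comparisons, 2 held with the estimated correlation, namely neutrophil and acute inflammatory genes with DSS in ATF6bKO. Members of a list past the threshold were counted over all genes tested and again adjusted over the list alone. A squamous epithelium list and a mast cell list were written after the data had been seen. Camera p-values are given for the latter only, unadjusted.

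A gene whose probe was not well above background on any array of a lower group has only a bound there. Its change is then also given as "at least N-fold". This compares the higher group's mean with the lower group's mean of, per array, the larger of the probe's own level and the lowest level among probes well above background on that array. A probe above background on 1 of 2 arrays of a lower group is stated where no bound is given.

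On each array 66.0% to 76.9% of spots were well above background and none was saturated. The number of arrays limits the precision: the median standard error of a log2 change was 0.26 within a genotype, 0.145 pooled over the knockouts and 0.368 for a difference between responses. In simulated DSS fits of 23200 genes, 67, 67 and 66 were changed by 1, 2 and 3 log2 units. The fits found 16.4%, 82.1% and 87.9% of these for ATF6aKO, 44.8%, 88.1% and 95.5% pooled, and 2.99%, 49.3% and 69.7% for ATF6aKO minus ATF6bKO. The real ATF6aKO and pooled fits called more genes, so these shares need not hold there.

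The alternatives were normexp background correction with an offset of 50, quantile normalization, the authors' value table, no filter and a strict filter on dim probes, the mean of a gene's probes, the replicate number as a block, fits of only the arrays compared, leaving out each array in turn, and camera with an estimated correlation. Normexp had been planned on mean signals, which the deposited files do not hold. Its version on median signals, the matching of value table columns to arrays and a fit without the WT arrays were added after the data were seen. Slides were told apart by scan date. The 4 arrays of each genotype had their own slide, with the earlier accession version for WT and the later for the knockouts. Genotype and slide therefore cannot be told apart in the genotype comparisons, while each DSS comparison lies within a slide. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and Matplotlib 3.10.9 read the files and drew the figures.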

Results

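Gene expression in the colon of male C57BL/6J mice was measured on 12 arrays from WT, ATF6aKO and ATF6bKO mice, untreated or given DSS, with 2 arrays per group. The series asks which genes respond to DSS in a manner that depends on each of the ATF6 proteins. The WT arrays carry conflicting labels, so their difference is described by the titles. Changes are in log2 units and p-values are from limma, adjusted over 23236 genes.

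Atf6 was lower in ATF6aKO than in WT over both treatments (log2 -3.92, SE 0.16, adjusted p = 4.06e-05). Its mean level was -3.13 and -3.16 in the UT and DSS arrays of ATF6aKO, with standard deviations of 0.132 and 0.103, against 0.73 to 1.18 in the other 4 groups, and the other Atf6 probe was lower too. Atf6b was lower in ATF6bKO than in WT (log2 -6.09, SE 0.69, adjusted p = 0.00186, at least 41.4-fold). The Atf6b probe was well above background on 0 of the 2 UT arrays and 1 of the 2 DSS arrays of ATF6bKO. Neither gene passed in the knockout of the other: Atf6 had a difference of 0.22 (SE 0.17, adjusted p = 0.357) in ATF6bKO, and Atf6b 0.34 (SE 0.24, adjusted p = 0.283) in ATF6aKO. Where the probes lie relative to the deleted parts of the genes is not given in the sources used here.

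**Figure D1:**
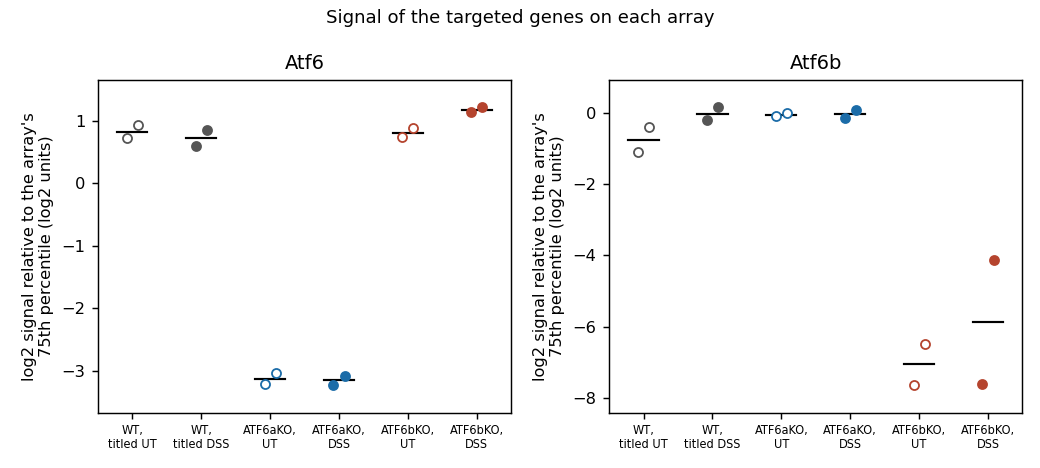
Level of Atf6 and Atf6b (log2 signal relative to the array's 75th percentile) on each of the 12 arrays by group, with points for arrays and bars for group means. Atf6 sits at -3.13 and -3.16 in the ATF6aKO groups, and Atf6b at -7.06 and -5.88 in the ATF6bKO groups.

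Over both knockouts, DSS was accompanied by higher transcripts of neutrophils and inflammation and by lower transcripts of crypt stem cells and dividing cells. S100a8 and S100a9, which encode calprotectin, a protein of neutrophils and of squamous epithelium, rose by 6.29 (SE 0.92, adjusted p = 0.00429, at least 55.3-fold) and 5.96 (SE 0.69, adjusted p = 0.00234). Lgr5, the receptor that marks crypt base stem cells, fell by 4.40 (SE 0.17, adjusted p = 0.000249, at least 20.1-fold). Axin2, a target of Wnt signalling in the crypt, fell by 3.43 (SE 0.138, adjusted p = 0.000249). Cldn2, a pore-forming protein of tight junctions, fell by 5.56 (SE 0.44, adjusted p = 0.00102). In total 6762 genes passed, of which 3080 rose and 3682 fell. Of the 6762, 1970 changed by at least 1 log2 unit. With normexp the balance turned, with 4926 that rose and 3430 that fell.

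Other genes with the largest rises included the pattern receptor Clec4e (4.87, adjusted p = 0.00136, at least 8.83-fold), the stromal protease Mmp3 (4.17, SE 0.17, adjusted p = 0.000249) and the cytokine Il22 (4.13, adjusted p = 0.00158, at least 3.77-fold). Wfdc21 (4.36, at least 9.41-fold), Acod1 (4.09, at least 14.1-fold), an enzyme of activated macrophages, and the chemokine Cxcl9 (4.02, adjusted p = 0.0233) also rose. The Cxcl9 probe was above background on 1 of the 2 ATF6bKO UT arrays, and without ATF6bKO DSS replicate 2 the gene did not pass (adjusted p = 0.0658, the highest over the omissions), nor did it without ATF6bKO DSS replicate 1 or ATF6aKO DSS replicate 1. Among the genes that fell furthest were Hamp, which encodes the iron hormone hepcidin (log2 -4.40, at least 14.3-fold), the oxidase Nox1 (log2 -4.22, at least 5.22-fold), the potassium channel subunit Kcne2 (log2 -3.97, at least 3.92-fold), Greb1 (log2 -3.81, at least 4.5-fold) and the histone gene H2bc23 (log2 -3.81, at least 8.67-fold). The urea cycle gene Otc fell as well (log2 -3.92, adjusted p = 0.0022), with 1 of the 2 DSS arrays of each knockout above background. By the rule these 16 genes, Axin2 left aside, had both DSS arrays on 1 side of both UT arrays in each knockout. The other 15 kept their call whichever array was left out. Without ATF6bKO DSS replicate 2 the number of genes past the threshold was 4472, and without ATF6aKO DSS replicate 1 it was 3856.

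**Figure D2:**
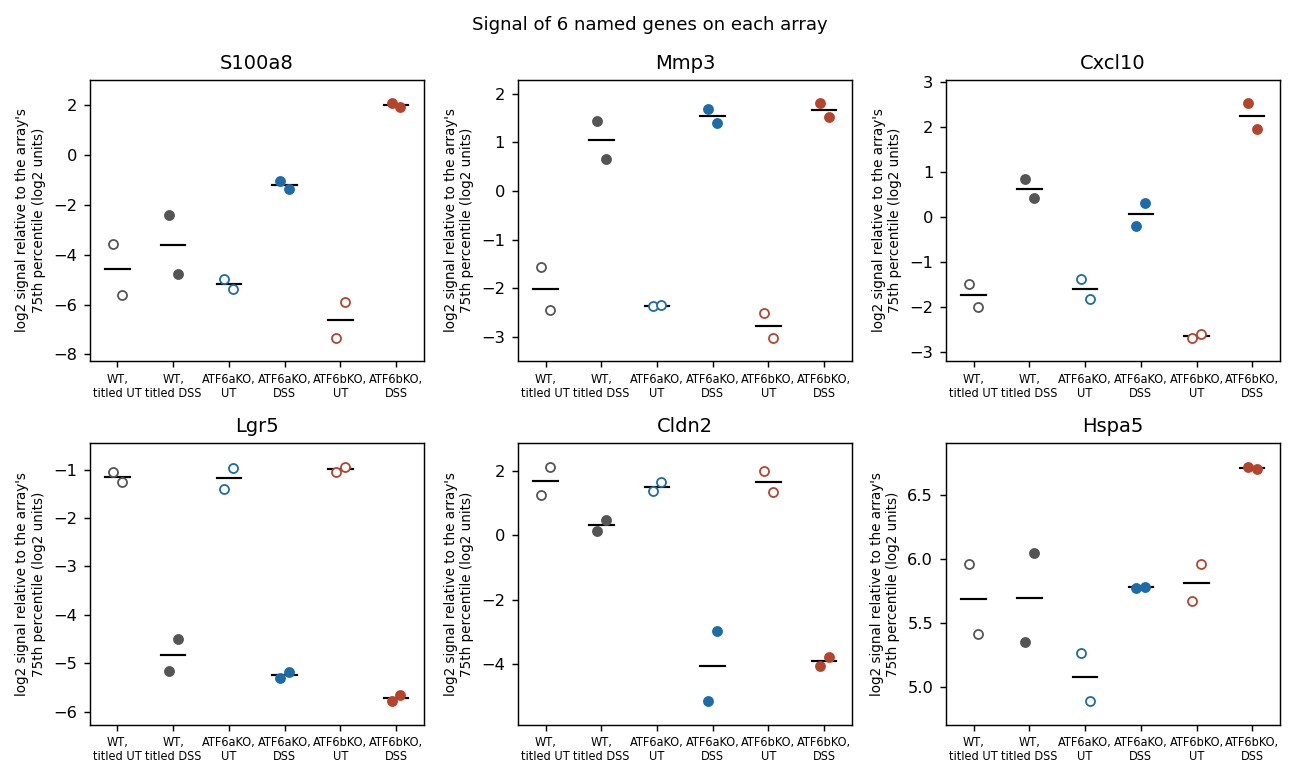
Level (log2 signal relative to the array's 75th percentile) of S100a8, Mmp3, Cxcl10, Lgr5, Cldn2 and Hspa5 on each of the 12 arrays by group. Over both knockouts S100a8 rose by 6.29 and Lgr5 fell by 4.40 log2 units.

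Among lists of cell type markers, 17 of 17 measured neutrophil genes rose (17 adjusted over the list alone, median 2.33, camera adjusted p = 2.59e-10), as did 18 of 19 of monocytes and macrophages (19 adjusted over the list alone, median 1.46, adjusted p = 5.59e-11). Of 19 T and NK cell genes 15 rose (18 adjusted over the list alone, median 1.66, adjusted p = 9.19e-08), among them the granzyme Gzma (2.78) and the chemokine Ccl5 (2.69). Without ATF6bKO DSS replicate 2 that count was 9. Fibroblast and matrix genes rose in 16 of 19 cases (18 adjusted over the list alone, median 0.752, adjusted p = 4.41e-10). Endothelial genes rose in 12 of 14 (13 adjusted over the list alone, median 0.719, adjusted p = 1.35e-07). Of 11 enteric neuron and glia genes 8 rose (9 adjusted over the list alone, median 0.517, adjusted p = 4.06e-05, 5 without ATF6aKO UT replicate 2). Smooth muscle and B cell genes were shifted upward with few members past the threshold: 2 of 16 (1 adjusted over the list alone, median 0.355, adjusted p = 0.00342) and 1 of 16 (0 adjusted over the list alone, median 1.11, adjusted p = 0.0017). The smooth muscle count ran from 1 without ATF6bKO UT replicate 2 to 8 without ATF6bKO DSS replicate 1, and the B cell count from 0 without ATF6bKO DSS replicate 1 to 5 without ATF6aKO DSS replicate 2. With an estimated correlation none of these 8 lists was called. Its adjusted p was 0.252 for neutrophil and for macrophage genes, 0.421 for T and NK cell genes, 0.227 for fibroblast, endothelial and neuron genes, 0.59 for smooth muscle and 0.479 for B cells.

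In the epithelium, 13 of 16 crypt base and stem cell genes fell and 1 rose (13 and 1 adjusted over the list alone, median -1.12, adjusted p = 1.03e-07, 0.136 with an estimated correlation). Enteroendocrine genes went the other way: 11 of 16 rose and 2 fell (12 and 2 adjusted over the list alone, median 0.659, adjusted p = 3.28e-05, 0.136 with an estimated correlation), among them the hormone genes Tac1 (1.38) and Gcg (1.30). Of 23 absorptive colonocyte genes 9 fell and 1 rose (9 and 1 adjusted over the list alone, median -0.475, adjusted p = 0.0363, 0.438 with an estimated correlation), including the sodium channel gene Scnn1b (log2 -1.64). Without ATF6bKO UT replicate 1 there were 4, and that call was lost (adjusted p = 0.0675), as it was without ATF6bKO DSS replicate 1 (0.0667), ATF6aKO UT replicate 2 (0.07) or ATF6aKO DSS replicate 2 (0.0526) and with the strict filter (0.0836). Of 17 goblet cell genes 3 fell, Atoh1 (log2 -1.24) and Ern2 (log2 -0.78) among them (3 adjusted over the list alone, median -0.163, adjusted p = 0.59). Adipocyte genes were not called (2 of 9 rose, 2 adjusted over the list alone, median 0.0777, adjusted p = 0.147). Nor were genes of small intestine and pancreas (1 of 9 fell, 1 adjusted over the list alone, median -0.0896, adjusted p = 0.929), where the test direction was opposite to the median.

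Among pathway lists, 20 of 23 acute inflammatory genes rose (23 adjusted over the list alone, median 2.35, adjusted p = 1.15e-13), including Il6 (3.75, at least 11.7-fold). Of 27 cell cycle genes 26 fell (26 adjusted over the list alone, median -1.63, adjusted p = 1.15e-13), including the cyclin Ccnb2 (log2 -2.15) and the kinase Aurkb (log2 -2.05). With an estimated correlation these had adjusted p = 0.227 and 0.252. Bub1 alone in the cell cycle list rose (0.78, adjusted p = 0.0488), with 1 of its 2 probes in that direction; with the mean of its probes it fell (log2 -0.66, adjusted p = 0.0304). Of 23 interferon-stimulated genes 17 rose (19 adjusted over the list alone, median 1.49, adjusted p = 4.28e-08, 0.421 with an estimated correlation), among them Iigp1 (3.33), and 10 did so without ATF6bKO DSS replicate 1. ER chaperones and folding enzymes, which include known targets of ATF6, rose in 6 of 20 cases (9 adjusted over the list alone, median 0.309, adjusted p = 0.000443, 0.479 with an estimated correlation), from 3 without ATF6aKO DSS replicate 1 to 10 without ATF6aKO UT replicate 1. Hspa5, the ER chaperone BiP, rose by 0.80 (SE 0.12, adjusted p = 0.00467) and Calr by 0.64 (SE 0.129, adjusted p = 0.0124). Genes of the translocon and secretory transport had 3 of 24 members higher (0 adjusted over the list alone, median 0.152, adjusted p = 0.00939, 0.59 with an estimated correlation), and the call was lost without ATF6bKO UT replicate 2 (0.052) and with normexp background correction (0.322).

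Antimicrobial and acute-phase epithelial genes went both ways, with 7 of 19 higher, such as Nos2 (2.35, at least 3.27-fold), and 3 lower, such as Saa1 (log2 -1.49). Adjusted over the list alone 11 rose and 4 fell (median 0.666, adjusted p = 0.0409, 0.477 with an estimated correlation). The call was lost without ATF6bKO UT replicate 1 (0.0832), ATF6bKO UT replicate 2 (0.0984) or ATF6bKO DSS replicate 1 (0.063). It was also lost with normexp (0.23), quantile normalization (0.0917) or the strict filter (0.194), and in the value table (0.0749). Xenobiotic and glutathione metabolism genes fell in 11 of 22 cases and rose in 1 (12 and 2 adjusted over the list alone, median -0.412, adjusted p = 0.0231, 0.571 with an estimated correlation), among them the glutathione transferase Gsta3 (log2 -2.54). Without ATF6aKO DSS replicate 1 there were 4, and without ATF6bKO UT replicate 1 the list was not called (0.0757). Targets of ATF4 and CHOP, transcription factors of a parallel stress pathway, had 7 of 25 members higher, such as Cebpb (1.14), and 3 lower, such as Cth (log2 -1.23; 8 and 3 adjusted over the list alone, median 0.41, adjusted p = 0.1). ER-associated degradation was not called (1 of 18 rose, 1 fell, 1 and 1 adjusted over the list alone, median 0.0911, adjusted p = 0.344). The same held for fatty acid oxidation (1 of 20 rose, 4 fell, 1 and 4 adjusted over the list alone, median -0.166, adjusted p = 0.15) and cholesterol synthesis (2 of 18 fell, 0 adjusted over the list alone, median -0.129, adjusted p = 0.143). Epithelial junctions were not called (median 0.121, mean -0.309, test upward, adjusted p = 0.676). Of 16, 2 rose and 4 fell (3 and 4 adjusted over the list alone), with Cldn15 lower (log2 -1.95) and Cldn8 higher (1.35).

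**Figure D3:**
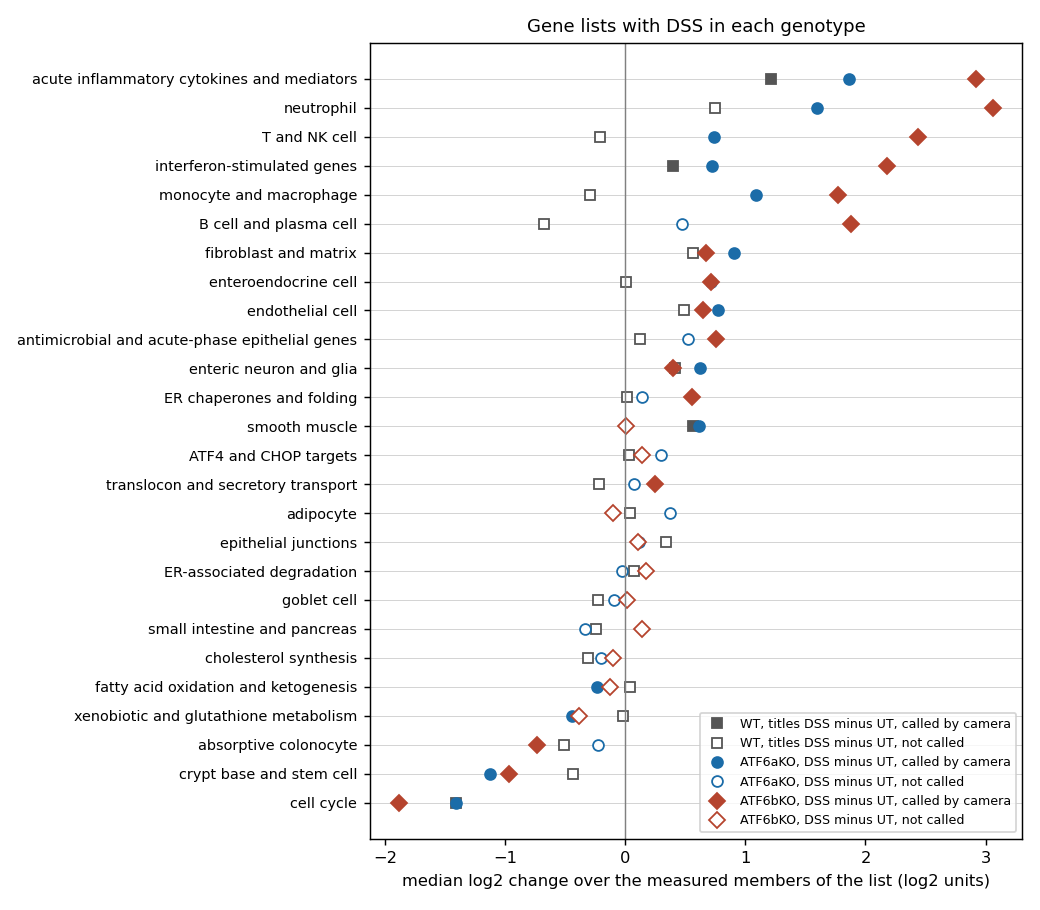
Median log2 difference between DSS and UT over the members of each of the 26 lists, for WT by the titles, ATF6aKO and ATF6bKO, with filled points for lists called by camera at its preset correlation. The neutrophil list has medians of 1.6 in ATF6aKO and 3.06 in ATF6bKO, and the cell cycle list -1.41 and -1.88.

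In ATF6aKO alone, genes of phagocytes and stroma were among those that rose furthest with DSS, and genes of crypt epithelium among those that fell furthest. Chil3, a lectin of activated macrophages, rose by 4.23 (SE 0.62, adjusted p = 0.0106), S100a9 by 4.15 (SE 0.59, adjusted p = 0.01) and Mmp3 by 3.90 (SE 0.35, adjusted p = 0.00336). Cldn2 fell by 5.55 (SE 0.61, adjusted p = 0.00436) and Lgr5 by 4.07 (SE 0.24, adjusted p = 0.00138). S100a8 (3.97), Clec4e (3.82, at least 5.81-fold), Chil4 (3.62, at least 6.32-fold), the protease Adamts4 (3.54) and the growth factor Ereg (3.41) rose as well. Kcne2 (log2 -5.19, at least 7.6-fold), Hamp (log2 -4.77, at least 12.5-fold), Otc (log2 -4.37), Nox1 (log2 -4.13, at least 6.03-fold), Clec2e (log2 -3.93, at least 3.17-fold) and Greb1 (log2 -3.67, at least 5.32-fold) fell. Of Adamts4, Ereg and Otc the lower group had 1 of 2 arrays above background. The 1473 genes past the threshold comprised 670 that rose and 803 that fell. There were 694 without a filter, 684 in a fit of only the arrays compared (388 rose and 296 fell) and 2915 without the WT arrays.

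Of the 16 genes named for ATF6aKO 10 kept their call whichever array was left out. Without ATF6aKO DSS replicate 1 the call was lost for S100a8 (adjusted p = 0.181), S100a9 (0.0665), Chil3 (0.0746), Chil4 (0.0996) and Adamts4 (0.0771), and without ATF6aKO UT replicate 1 it was lost for Hamp (0.0623), which are the highest values over the omissions. Calls were lost for 3 and 5 of the 16 genes without the UT arrays of ATF6aKO in turn, and for 6 and 2 without its DSS arrays. The number of genes past the threshold was 188 and 215 without the first and the second UT array of ATF6aKO, 183 and 443 without its DSS arrays, and 3454 without either WT array titled UT.

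Crypt base and stem cell genes fell in 10 of 16 cases in ATF6aKO (11 fell and 1 rose adjusted over the list alone, median -1.13, adjusted p = 7.47e-10, 0.119 with an estimated correlation). Cell cycle genes fell in 17 of 27 (24 adjusted over the list alone, median -1.41, adjusted p = 3.61e-17, 0.148 with an estimated correlation). The crypt and cell cycle counts were 5 and 1 without ATF6aKO UT replicate 1. Axin2 (log2 -3.30) and Aurkb (log2 -2.01) were among them. Acute inflammatory genes rose in 11 of 23 cases (17 adjusted over the list alone, median 1.86, adjusted p = 2.49e-11, 0.119 with an estimated correlation), such as Il22 (3.39, at least 2.39-fold) and the neutrophil attractant Cxcl1 (2.81). Neutrophil genes rose in 9 of 17 (12 adjusted over the list alone, median 1.6, adjusted p = 3.85e-10, 0.119 with an estimated correlation), and without ATF6aKO UT replicate 1 these counts were 2 and 1. Further lists were shifted upward. In the fibroblast and matrix list 6 of 19 genes rose (16 adjusted over the list alone, median 0.905, adjusted p = 4.42e-10). Of 16 enteroendocrine genes 7 rose and 1 fell (7 and 2 adjusted over the list alone, median 0.715, adjusted p = 0.000428). Monocyte and macrophage genes rose in 3 of 19 cases (14 adjusted over the list alone, median 1.09, adjusted p = 7.14e-08) and endothelial genes in 3 of 14 (8 adjusted over the list alone, median 0.77, adjusted p = 5.78e-06). Enteric neuron and glia genes rose in 3 of 11 cases (5 adjusted over the list alone, median 0.626, adjusted p = 3.49e-05) and interferon-stimulated genes in 3 of 23 (5 adjusted over the list alone, median 0.726, adjusted p = 2.16e-05). The adjusted p of these 6 lists with an estimated correlation lay between 0.148 and 0.267. Over the omissions the lowest counts were 1 for fibroblast genes without ATF6aKO UT replicate 2 and 0 for the other 5 lists without ATF6aKO UT replicate 1 or ATF6aKO DSS replicate 1.

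Smooth muscle genes were also called (2 of 16 rose, 7 adjusted over the list alone, median 0.617, adjusted p = 1.11e-05, 0.413 with an estimated correlation). The same held for T and NK cell genes (0 of 19 rose, 8 adjusted over the list alone, median 0.741, adjusted p = 3.68e-05, 0.401 with an estimated correlation). Each had 0 to 5 members past the threshold over the omissions, with 5 without either WT array titled UT. Lower lists were xenobiotic and glutathione metabolism genes (4 of 22 fell and 1 rose, median -0.442, adjusted p = 0.0298, 0.589 with an estimated correlation) and fatty acid oxidation (0 of 20 fell and 1 rose, median -0.233, adjusted p = 0.0449, 0.596 with an estimated correlation). Both calls were lost without ATF6aKO UT replicate 2 (0.204 and 0.584), without ATF6aKO DSS replicate 1 (0.0578 and 0.165), with quantile normalization (0.104 and 0.105) and with the strict filter (0.0673 and 0.0706). The fatty acid oxidation call was also lost without ATF6bKO DSS replicate 1 or replicate 2 (0.0527) and with the mean of a gene's probes (0.0502). ER chaperones had 0 of 20 members past the threshold in ATF6aKO (0 adjusted over the list alone, median 0.139, adjusted p = 0.16). Hspa5 had a value of 0.70 (SE 0.274, adjusted p = 0.165) there. Epithelial junction genes had a median of 0.116 and a mean of -0.278, with 1 higher and 2 lower.

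In ATF6bKO, neutrophil and interferon-inducible genes and genes of keratinizing squamous epithelium were among those that rose furthest with DSS. S100a8 rose by 8.60 (SE 0.85, adjusted p = 0.00145, at least 195-fold) and S100a9 by 7.78 (SE 0.59, adjusted p = 0.000711). Ido1, an interferon-inducible enzyme that degrades tryptophan, rose by 6.49 (SE 0.98, adjusted p = 0.00481), and Cxcl9 by 6.37 (SE 0.677, adjusted p = 0.00173, with 1 of 2 UT arrays above background). Lgr5 fell by 4.73 (SE 0.24, adjusted p = 0.000373, at least 24.2-fold) and Cldn2 fell by 5.57 (SE 0.61, adjusted p = 0.0018). The genes past the threshold numbered 2990, of which 1323 rose and 1667 fell. There were 1796 with normexp (979 rose and 817 fell), 1803 in a fit of only the arrays compared and 4589 without the WT arrays.

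Genes of cornified epithelium rose with large standard errors: Crct1 (7.53, SE 1.65, adjusted p = 0.0199, at least 48.7-fold) and Sprr2d (7.28, SE 1.11, adjusted p = 0.00494, at least 36-fold). Lce3f (6.83, SE 1.58, adjusted p = 0.0244, at least 36.7-fold), Krt1 (6.78, SE 1.52, adjusted p = 0.0217, at least 31.5-fold) and Krtdap (6.57, SE 1.43, adjusted p = 0.0193, at least 75.5-fold) did so too. Without ATF6bKO UT replicate 1 or replicate 2 the calls of Crct1 (up to 0.0888), Krt1 (up to 0.102), Krtdap (up to 0.0846) and Lce3f (up to 0.107) were lost. The squamous epithelium list was written after the data had been seen, so its camera p-values are no independent test and are left out. In it 14 of 20 measured genes rose with DSS in ATF6bKO (median 5.52), against 0 of 20 in ATF6aKO (median 0.327). Over both knockouts 2 rose (median 2.93). In ATF6aKO minus ATF6bKO 0 passed (median -4.63). Its median level was 2.31 on ATF6bKO DSS replicate 2 and -2.42 on replicate 1, and between -6.42 and -5.08 on the other 10 arrays. Prr18 (log2 -4.68, at least 5.56-fold), Nox1 (log2 -4.31, at least 4.53-fold), Pgk2 (log2 -4.26, at least 4.54-fold), H2bc23 (log2 -4.13, at least 8.5-fold), Hamp (log2 -4.03, 1 of 2 DSS arrays above background) and Nags (log2 -4.00, at least 3.96-fold), the enzyme that makes the activator of the urea cycle, were the others that fell furthest in ATF6bKO.

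**Figure D4:**
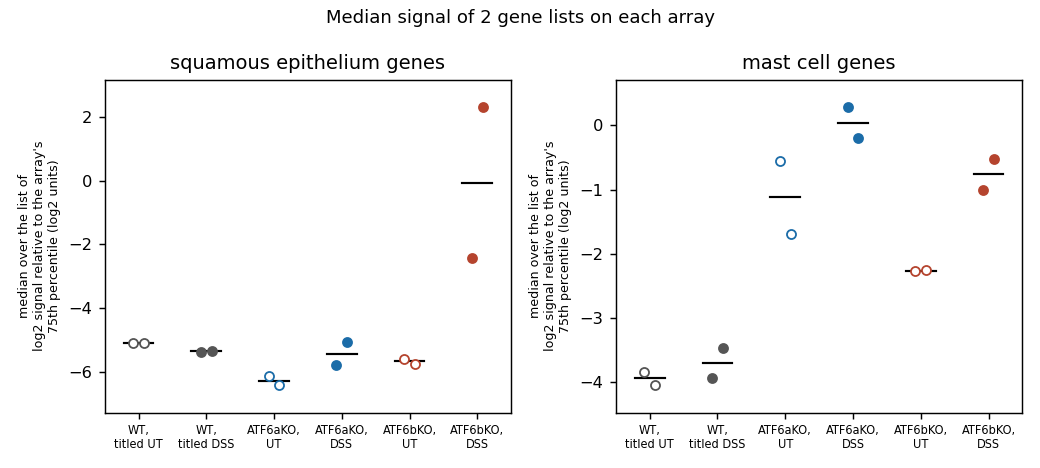
Median level of the squamous epithelium list and of the mast cell list (log2 signal relative to the array's 75th percentile) on each of the 12 arrays by group. The squamous median is 2.31 and -2.42 on the ATF6bKO DSS arrays and at most -5.08 elsewhere, and the mast cell median is -4.04 to -3.46 on the WT arrays.

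Interferon-stimulated genes rose in 19 of 23 cases in ATF6bKO (20 adjusted over the list alone, median 2.18, adjusted p = 4.58e-20, 0.0526 with an estimated correlation), among them the GTPase Iigp1 (5.11, SE 0.701, adjusted p = 0.00341), with 13 as the lowest count, without ATF6bKO UT replicate 1. Acute inflammatory genes rose in 18 of 23 (23 adjusted over the list alone, median 2.92, adjusted p = 3.34e-21, 0.0402 with an estimated correlation), such as Ifng (5.22, at least 22.1-fold) and Il6 (4.99, at least 24.1-fold). Neutrophil genes rose in 15 of 17 (17 adjusted over the list alone, median 3.06, adjusted p = 6.25e-19, 0.0402 with an estimated correlation). T and NK cell genes rose in 16 of 19 (19 adjusted over the list alone, median 2.44, adjusted p = 6.18e-17, 0.0898 with an estimated correlation), such as Ccl5 (3.71) and Gzma (3.49). Macrophage genes rose in 14 of 19 (16 adjusted over the list alone, median 1.77, adjusted p = 6.09e-14, 0.102 with an estimated correlation), such as the Fc receptor Fcgr1 (2.78). B cell and plasma cell genes rose in 5 of 16 (10 adjusted over the list alone, median 1.88, adjusted p = 1.68e-06, 0.165 with an estimated correlation). Without ATF6bKO UT replicate 1 the macrophage and B cell counts were 7 and 0. Without ATF6bKO DSS replicate 2, the array with the highest squamous signal, 12 neutrophil, 13 T and NK cell, 14 interferon-stimulated and 14 inflammatory genes passed.

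Cell cycle genes fell in 24 of 27 cases in ATF6bKO and 1 rose (26 and 1 adjusted over the list alone, median -1.88, adjusted p = 2.78e-16, 0.102 with an estimated correlation), with 13 without ATF6bKO DSS replicate 2. Crypt base genes fell in 10 of 16 (12 fell and 2 rose adjusted over the list alone, median -0.968, adjusted p = 3.96e-07, 0.0898 with an estimated correlation), and 6 did so without ATF6bKO UT replicate 1. Absorptive colonocyte genes fell in 6 of 23 and rose in 1 (10 and 1 adjusted over the list alone, median -0.736, adjusted p = 0.0159, 0.297 with an estimated correlation), a call that was lost without ATF6bKO UT replicate 1 (0.0807), where 1 gene fell. ER chaperones rose in 4 of 20 cases (8 adjusted over the list alone, median 0.557, adjusted p = 6.85e-06, 0.195 with an estimated correlation), with Hyou1 at 1.04 (SE 0.247, adjusted p = 0.027) and Creld2 at 0.90 (SE 0.189, adjusted p = 0.0167). Without ATF6bKO UT replicate 1 or ATF6bKO DSS replicate 2 the count was 0, without either WT array titled UT it was 8, and in the fit without the WT arrays 11. Enteroendocrine genes rose in 5 of 16 cases (7 adjusted over the list alone, median 0.714, adjusted p = 8.81e-05) and fibroblast genes in 5 of 19 (9 adjusted over the list alone, median 0.67, adjusted p = 6.18e-08). Endothelial genes rose in 3 of 14 cases (7 adjusted over the list alone, median 0.644, adjusted p = 1.36e-05) and enteric neuron and glia genes in 2 of 11 (3 adjusted over the list alone, median 0.401, adjusted p = 0.00209). Antimicrobial genes rose in 6 of 19 cases (10 rose and 3 fell adjusted over the list alone, median 0.753, adjusted p = 5e-04). With an estimated correlation the adjusted p of these 5 lists lay between 0.0898 and 0.195. Over the omissions the lowest counts were 1 for enteroendocrine genes without ATF6bKO DSS replicate 1, and 0 for endothelial genes without ATF6bKO UT replicate 1. They were 0 for neuron genes without ATF6bKO DSS replicate 2 and 3 for antimicrobial genes without ATF6bKO UT replicate 1. The translocon list was called at a median of 0.246 (adjusted p = 0.0059, 1 of 24 rose, 0.401 with an estimated correlation), but not with normexp (0.1).

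Of the 16 genes named for ATF6bKO 12 kept their call whichever array was left out. The number of genes past the threshold was 1273 and 1831 without the UT arrays of ATF6bKO in turn, 1621 and 1093 without its DSS arrays, and 5282 without either WT array titled UT.

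The responses of the knockouts shared most of their direction. Of genes past the threshold in both, 371 rose in both, 582 fell in both and 1 went opposite ways, and the changes correlated across genes (r = 0.614), which are not independent replicates. In the difference between the responses, ATF6aKO minus ATF6bKO, 0 genes passed by limma, with 1856 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0737, for Prr18 (4.56, SE 0.48). Zcwpw1 (2.25, SE 0.28, adjusted p = 0.144) and the clock gene Npas2 (1.76, SE 0.28, adjusted p = 0.302) had positive values. The chemokine gene Cxcl10 (log2 -3.23, SE 0.42, adjusted p = 0.144), Plet1 (log2 -3.84, SE 0.55, adjusted p = 0.202) and the bile acid binding protein gene Fabp6 (log2 -3.21, SE 0.46, adjusted p = 0.202) had negative ones. The Prr18 probe was not well above background in the DSS arrays of ATF6bKO, so its 4.56 is a fitted value, and the Zcwpw1 probe was not so on both arrays of any of the 4 groups. Without ATF6bKO DSS replicate 1, 83 genes passed (5 higher and 78 lower), and without either WT array titled DSS 4 did. Quantile normalization gave 5, the values of the authors gave 2, and the fit of only the arrays compared gave 4. A gene absent from these calls may differ by an amount that was not detectable here.

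As groups, interferon-stimulated genes were shifted downward in this difference: 23 of 23 had negative values (median -1.34, camera adjusted p = 3.85e-24), 0 passed over all genes and 16 did adjusted over the list alone. Inflammatory genes (23 of 23 negative, median -1, adjusted p = 1.04e-13, 7 adjusted over the list alone) and neutrophil genes (median -1.47, adjusted p = 1.52e-14, 8 adjusted over the list alone) were shifted the same way. So were T and NK cell genes (median -1.43, adjusted p = 5.43e-17, 10 adjusted over the list alone), B cell genes (median -1.35, adjusted p = 2.33e-06) and macrophage genes (median -0.618, adjusted p = 2.01e-06). ER chaperones (18 of 20 negative, median -0.338, adjusted p = 5.63e-05), ER-associated degradation (median -0.157, adjusted p = 0.00298) and translocon genes (median -0.172, adjusted p = 0.0159) were shifted downward too. Further shifts downward were those of antimicrobial genes (median -0.293, adjusted p = 0.000116), fatty acid oxidation (median -0.237, adjusted p = 0.0139), goblet cell genes (median -0.0888, adjusted p = 0.0296) and small intestine and pancreas genes (median -0.426, adjusted p = 0.049). Smooth muscle (median 0.598, adjusted p = 0.000135) and cell cycle genes (median 0.441, adjusted p = 0.0345) were shifted upward. With an estimated correlation none of these 15 calls held. The adjusted p was then 0.0627 for interferon-stimulated, inflammatory and neutrophil genes, 0.0966 for antimicrobial genes, 0.105 for T and NK cell genes, and 0.197 to 0.826 for the others. Median, mean and test differed in sign for the uncalled crypt, fibroblast, ATF4 and CHOP, cholesterol, junction and xenobiotic lists.

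**Figure D5:**
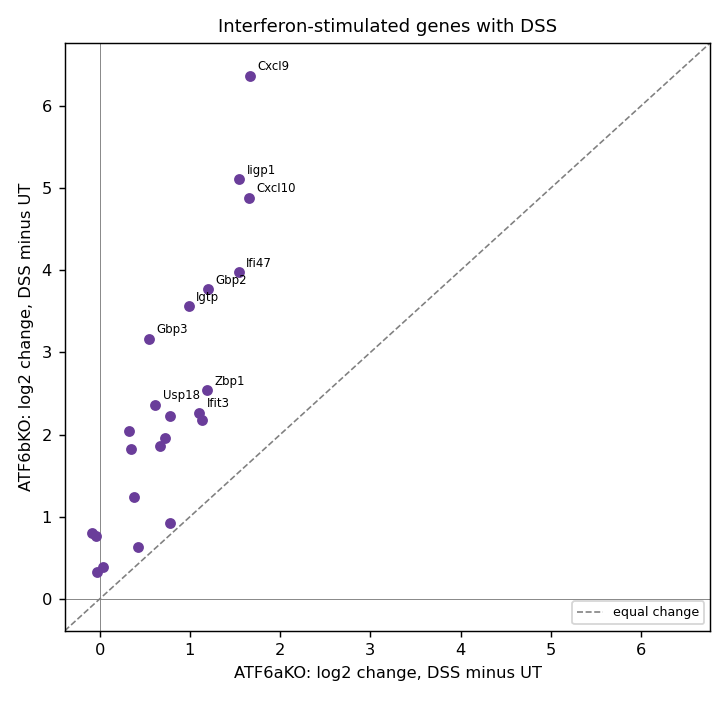
Change with DSS (log2 units) of each of the 23 interferon-stimulated genes in ATF6bKO, vertical axis, against that in ATF6aKO, horizontal axis, with 1 point per gene and a dashed line for equal change. The 23 points lie above the line, and the list medians are 2.18 in ATF6bKO and 0.726 in ATF6aKO.

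Several of these 15 calls rested on single arrays. The goblet cell call was lost without ATF6bKO UT replicate 1 (0.228), ATF6bKO DSS replicate 2 (0.152), ATF6aKO UT replicate 2 (0.0501) or ATF6aKO DSS replicate 1 (0.0946), and the smooth muscle call without ATF6bKO DSS replicate 1 (0.0861). For the translocon these were ATF6bKO UT replicate 2 (0.0565), ATF6bKO DSS replicate 1 (0.0871), ATF6aKO UT replicate 1 (0.502) and ATF6aKO DSS replicate 1 (0.0656). Cell cycle genes lost theirs without either WT array titled UT (0.0755), ATF6bKO UT replicate 1 (0.184), ATF6bKO DSS replicate 2 (0.714), ATF6aKO UT replicate 2 (0.497) or ATF6aKO DSS replicate 1 (0.951, median 0.149). Fatty acid oxidation lost its call without ATF6bKO UT replicate 2 (0.501), ATF6bKO DSS replicate 2 (0.0639), ATF6aKO UT replicate 2 (0.4) or ATF6aKO DSS replicate 1 (0.157), and the small intestine list in 9 of the 12 omissions (up to 0.295), as well as with normexp (0.189), without a filter (0.152, median 0.0191) and with the strict filter (0.99, median 0.196). With quantile normalization the calls of goblet cell genes (0.0901), translocon genes (0.149), fatty acid oxidation (0.128) and ER-associated degradation (0.0543) were lost. Cell cycle genes lost theirs with normexp (0.231), and in the fit of only the arrays compared both cell cycle (0.0963) and small intestine genes (0.104) did.

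In the WT arrays titled DSS, against those titled UT, the acute inflammatory list was shifted upward and the cell cycle list downward. This is the direction of both lists with DSS in the knockouts. Clec4e was higher by 3.80 (SE 0.37, adjusted p = 0.00124, at least 3.75-fold), Mmp3 by 3.07 (SE 0.35, adjusted p = 0.00173) and the cytokine Il6 by 3.25 (SE 0.47, adjusted p = 0.00287, at least 9.16-fold). Lgr5 (log2 -3.68, SE 0.24, adjusted p = 0.000644) and Hamp were lower (log2 -4.61, SE 0.69, adjusted p = 0.00325, at least 6.12-fold). Other genes higher in the arrays titled DSS were Tcf7l1 (3.36, adjusted p = 0.000887), Tmem145 (3.25), the hyaluronan synthase Has1 (3.25), Zc3h13 (3.06) and Chrdl2 (3.06), where Tmem145 and Has1 had 1 of 2 arrays titled UT above background. Lower were the olfactory receptor genes Olfr134 (log2 -6.23, at least 17.2-fold) and Olfr902 (log2 -3.73, at least 3.05-fold), Pla2g4c (log2 -4.55, SE 1.41, adjusted p = 0.039, at least 6.72-fold), Spaca1 (log2 -3.92, at least 5.8-fold), the pancreatic lipase gene Pnliprp2 (log2 -3.59) and Cpn1 (log2 -3.38). In total 7375 genes passed, 3426 higher and 3949 lower in the arrays titled DSS. A fit of only the 4 WT arrays gave 635, with the balance turned to 395 higher and 240 lower.

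The call of Pla2g4c was lost in 6 of 12 omissions (adjusted p up to 0.169) and that of Spaca1 in 2 (up to 0.0659), while 14 of the 16 genes kept theirs. Without replicate 1 or replicate 2 titled DSS the number of genes past the threshold was 2970 or 3037. Of the 2459 genes called in WT and in the pooled knockouts, 1963 (79.8%) had the same direction when WT was read by the titles, and 4916 genes called in WT were not called in the knockouts. Across genes the WT difference correlated with the response in ATF6aKO at r = 0.321 and in ATF6bKO at r = 0.132.

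By lists, cell cycle genes were lower in 19 of 27 cases in the WT arrays titled DSS (21 adjusted over the list alone, median -1.41, adjusted p = 1.47e-08), with 11 without replicate 2 titled DSS. Acute inflammatory genes were higher in 12 of 23 (12 adjusted over the list alone, median 1.21, adjusted p = 6.25e-05), with 5 without replicate 1 titled DSS. Smooth muscle genes (5 of 16 higher, 5 adjusted over the list alone, median 0.564, adjusted p = 0.0061) and interferon-stimulated genes (5 of 23, 4 adjusted over the list alone, median 0.397, adjusted p = 0.0151) were also called. Smooth muscle genes lost the call without replicate 1 titled UT (0.0514), and interferon-stimulated genes without replicate 2 titled UT (0.386). None of these 4 calls held with an estimated correlation (adjusted p = 0.865). Crypt base and stem cell genes were not called in WT (2 of 16 higher and 5 lower, median -0.435, adjusted p = 0.13). Nor were 4 lists whose medians were opposite to those called over both knockouts: macrophage (-0.292, 0.547), B cell (-0.678, 0.151), T and NK cell (-0.21, 0.526) and translocon genes (-0.218, 0.0873, 7 of 24 lower). The smooth muscle count ran from 1 without replicate 1 titled DSS to 10 without replicate 2 titled UT. ER chaperones went both ways, with 3 of 20 higher, such as Hyou1 (1.24), and 3 lower, such as Cnpy2 (log2 -1.20; median 0.0177, adjusted p = 0.922). ER-associated degradation did so too, with 4 of 18 higher, such as Edem1 (1.43), and 4 lower, such as Erlec1 (log2 -1.01; median 0.0766, adjusted p = 0.622). The sign differed between median, mean and test for ER chaperones and for the enteroendocrine, ATF4 and CHOP, and xenobiotic lists.

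Responses of the knockouts minus the WT difference depend on which WT label holds. With WT read by the titles, 1777 genes passed for ATF6aKO (830 higher and 947 lower) and 3398 for ATF6bKO (1460 higher and 1938 lower). There were 260 without a filter, 2846 with the strict filter, 868 in the value table and 158 with only the arrays compared for ATF6aKO, and 1487 without a filter and 890 with only the arrays compared for ATF6bKO. Read by the descriptions there were 6479 and 6799, the latter 4199 with only the arrays compared. By the titles the genes named by the rule for ATF6aKO included Olfr134 (5.22), Spaca1 (5.09), Wfdc21 (4.29, adjusted p = 0.0494), Epyc (4.22, adjusted p = 0.0433), Spag17 (log2 -4.38) and Cldn2 (log2 -4.18, SE 0.86, adjusted p = 0.0301). For ATF6bKO they included Lce3f (9.07), Krtdap (8.28), Kprp (8.18), Krt1 (7.87), S100a8 (7.61, adjusted p = 0.0105), Prr18 (log2 -6.31, SE 0.48, adjusted p = 0.00462) and Pgk2 (log2 -5.44, SE 0.82, adjusted p = 0.00978). Of the 10 genes named for each, 0 kept their call in every omission for ATF6aKO, and 4 did for ATF6bKO (Nags, Pgk2, Prr18 and S100a8). By the descriptions the WT difference has the opposite sign. The genes named then included Clec4e (7.62, adjusted p = 0.000569), Hamp (log2 -9.38, adjusted p = 0.00111), Lgr5 (log2 -7.74, adjusted p = 0.000107) and Olfr134 (log2 -7.24, adjusted p = 0.00375) for ATF6aKO. They included Clec4e (9.73, adjusted p = 0.000165), Hamp (log2 -8.64, adjusted p = 0.00108) and Lgr5 (log2 -8.41, adjusted p = 5.21e-05) for ATF6bKO. Of 10 such genes each, 8 and 10 kept their call in every omission. Except for Cldn2 and, in ATF6aKO, Lgr5, each gene named here was well above background on no array of at least 1 group compared (3 of 4 groups for Olfr134 and Spaca1 in ATF6aKO). Such sizes are fitted values and neither they nor their order is exact.

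The counts by the titles moved with single arrays. For ATF6aKO they ran from 0 without ATF6aKO UT replicate 2 to 7620 without replicate 2 titled UT, with at most 307 without any 1 of the ATF6aKO arrays or those titled DSS. For ATF6bKO they ran from 735 without replicate 2 titled DSS to 8976 without replicate 2 titled UT. By the descriptions they ran from 2951 without ATF6aKO DSS replicate 1 to 10149 without replicate 2 titled UT, and from 3958 without ATF6bKO DSS replicate 2 to 10030.

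By the titles, T and NK cell genes had larger changes in ATF6bKO than in WT (16 of 19 higher, 18 adjusted over the list alone, median 2.4, adjusted p = 7.35e-11). So did macrophage genes (13 of 19, 17 adjusted over the list alone, median 1.92, adjusted p = 6.87e-09) and neutrophil genes (11 of 17, 13 adjusted over the list alone, median 2.87, adjusted p = 1.97e-09). Interferon-stimulated (13 of 23, 15 adjusted over the list alone, median 1.75, adjusted p = 3.48e-07) and inflammatory genes (9 of 23, 14 adjusted over the list alone, median 1.66, adjusted p = 6.76e-07) were also shifted upward. B cell (median 2.41), antimicrobial (median 1.39), ER chaperone (median 0.62), translocon (median 0.537), enteroendocrine (median 0.64) and fibroblast genes (median 0.563) were shifted the same way, and crypt base genes downward (median -0.709, adjusted p = 0.00499). Lowest counts were 8, 2 and 6 for T and NK cell, macrophage and interferon-stimulated genes without ATF6bKO DSS replicate 2, and 6 and 4 for neutrophil and inflammatory genes without replicate 2 titled DSS. The fibroblast call was lost without replicate 2 titled DSS (0.0502), replicate 1 titled UT (0.0571) or ATF6bKO UT replicate 2 (0.056) and with normexp (0.141), and the antimicrobial call with quantile normalization (0.144). No list of this comparison was called with an estimated correlation, where adjusted p was 0.282 at the lowest.

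By the descriptions, 11 and 14 lists were called. Cell cycle genes had medians of -2.78 and -3 for ATF6aKO and ATF6bKO (adjusted p = 1.36e-14 and 1.01e-14), inflammatory genes 3.07 and 4.07 (2.42e-09 and 1.01e-14) and crypt base genes -1.52 and -1.48 (6.19e-05 and 0.000179), none with an adjusted p under 0.138 with an estimated correlation.

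For ATF6aKO minus WT by the titles, macrophage (median 1.32, adjusted p = 0.000198), neutrophil (median 1.24, adjusted p = 0.00714), B cell (median 1.04, adjusted p = 0.04) and T and NK cell genes (median 0.968, adjusted p = 0.00209) were shifted upward. So were fibroblast (median 0.76, adjusted p = 0.0308), enteroendocrine (median 0.592, adjusted p = 0.0308) and translocon genes (median 0.387, adjusted p = 0.0308), while crypt base genes were shifted downward (median -0.778, adjusted p = 0.00209). With an estimated correlation the adjusted p was 0.927 for each of these 8 lists. Without replicate 2 titled UT the calls of the enteroendocrine (0.0969), neutrophil (0.0969), B cell (0.287), T and NK cell (0.14) and translocon (0.0916) lists were lost. Fibroblast genes lost theirs without replicate 2 titled DSS (0.0816), replicate 1 titled UT (0.0713), ATF6aKO UT replicate 2 (0.0568) or ATF6aKO DSS replicate 1 (0.122). Enteroendocrine and translocon genes lost theirs without replicate 1 titled DSS (0.0781 and 0.154) or ATF6aKO UT replicate 2 (0.0568 and 0.189), and enteroendocrine genes without ATF6aKO DSS replicate 1 (0.0886). The B cell call was lost without replicate 2 titled DSS (0.0974), ATF6aKO UT replicate 1 (0.243) or ATF6aKO DSS replicate 1 (0.222). Quantile normalization removed the enteroendocrine (0.0696) and translocon (0.251) calls, normexp the translocon call (0.102), the strict filter the neutrophil call (0.0949), and the mean of a gene's probes the enteroendocrine and B cell (0.0537) and translocon (0.105) calls. The value table did not give the B cell and fibroblast calls (0.0584) or the translocon call (0.0813), and the fit of only the arrays compared did not give the translocon call (0.0544).

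Among the largest genotype differences over both treatments, lectin and glucuronidation genes were lower and mast cell protease genes higher in both knockouts. Each slide held 1 genotype, and spike-in signal also split WT from both. Reg3b, an antimicrobial lectin of epithelium, was lower in ATF6aKO (log2 -10.16, SE 0.47, adjusted p = 5.91e-05, at least 630-fold) and in ATF6bKO (log2 -10.41, SE 0.96, adjusted p = 0.00103, at least 625-fold). The mast cell chymase genes Cma2 (6.68, SE 0.38, adjusted p = 5.91e-05, and 5.27, SE 0.42, adjusted p = 0.000718) and Mcpt9 (7.22, at least 44.8-fold, and 5.58, at least 14.4-fold) were higher in ATF6aKO and in ATF6bKO. Mcpt1 (6.52) and Mcpt4 (6.40) were among the largest differences in ATF6aKO. Ugt2b5 (log2 -6.97, at least 56.8-fold, and log2 -7.22, at least 51.1-fold), Ugt2b36 (log2 -6.07, at least 31.4-fold, and log2 -6.77, at least 27.9-fold) and Adam18 (log2 -6.17, at least 22.4-fold, and log2 -6.29, at least 16.4-fold) were lower in both, Ugt2b38 (log2 -5.90, at least 34.1-fold) in ATF6aKO and Reg3g (log2 -7.55, at least 121-fold) in ATF6bKO. Syt10 (6.85) was higher in ATF6aKO, and Kcnj16 (6.45, 1 of 2 WT arrays titled DSS above background), Pramel39 (5.26, at least 22-fold) and the carboxylesterase gene Ces1c (5.09) in ATF6bKO. Each of the 10 genes named for each knockout kept its call whichever array was left out. The mast cell list was written after these genes had been seen, so its p-values are no independent test. In it 11 of 14 measured genes were higher in ATF6aKO (median 2.81, unadjusted camera p = 7.54e-09, 0.0105 with an estimated correlation) and 10 of 14 in ATF6bKO (median 2.29, unadjusted p = 1.23e-06, 0.0256 with an estimated correlation). With normexp the medians were 1.86 and 1.59.

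Past the threshold were 8193 genes for ATF6aKO (3411 higher and 4782 lower) and 6827 for ATF6bKO (3181 higher and 3646 lower). This balance depends on the processing: with normexp 4248 were higher and 2663 lower in ATF6aKO, and 9486 and 2853 of 12339 in ATF6bKO, and with the values of the authors 10539 and 1580, and 9588 and 1059 of 10647. Without ATF6aKO UT replicate 1 the first count was 5391, and without ATF6bKO UT replicate 2 the second was 4134. Absorptive colonocyte genes were lower in 12 of 23 cases and higher in 2 in ATF6aKO (14 and 2 adjusted over the list alone, median -0.968, adjusted p = 0.00325, 0.673 with an estimated correlation). They were lower in 15 of 23 in ATF6bKO (16 adjusted over the list alone, median -1.24, adjusted p = 5.86e-05, 0.401 with an estimated correlation). The bile acid transporter gene Slc51a was lower in both (log2 -4.09, at least 9.63-fold, and log2 -4.42, at least 6.73-fold). Enteroendocrine genes were lower in 6 of 16 and higher in 1 in ATF6aKO (median -0.475, adjusted p = 0.0435, 0.938 with an estimated correlation). In ATF6bKO 11 of 16 were lower and 1 higher (median -0.892, adjusted p = 0.000135, 0.76 with an estimated correlation), with the neurotensin gene Nts at -4.21 and -4.19. Fatty acid oxidation genes were lower in 9 of 20 cases in each (medians -0.427 and -0.44, adjusted p = 0.00633 and 0.00615, 0.938 and 0.76 with an estimated correlation). Targets of ATF4 and CHOP were higher in 12 of 25 and lower in 3 in ATF6aKO (13 and 3 adjusted over the list alone, median 0.831, adjusted p = 0.00173, 0.756 with an estimated correlation), with the cystine transporter Slc7a11 at 3.13 and Chac1 at 3.01. In ATF6bKO 5 were higher and 4 lower (median 0.183, adjusted p = 0.455). ER chaperones were not called in either (2 of 20 higher and 1 lower in ATF6aKO, adjusted p = 0.313). Nor were antimicrobial genes, with 4 of 19 higher and 3 lower in ATF6aKO (median 0.12, mean -0.53, adjusted p = 0.852) and 5 higher and 2 lower in ATF6bKO (median 0.135, mean -0.399, adjusted p = 0.428).

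Macrophage (6 of 19 and 4 of 19 higher, medians 0.751 and 0.672, adjusted p = 0.00325 and 0.0272) and endothelial genes (4 of 14 and 3 of 14, medians 0.426 and 0.501, adjusted p = 0.0363 and 0.0226) were shifted upward in ATF6aKO and ATF6bKO. B cell genes (6 of 16 higher and 1 lower, median 0.915, adjusted p = 0.0136) and ER-associated degradation (5 of 18, 1 adjusted over the list alone, median 0.414, adjusted p = 0.0425) were so in ATF6aKO. In ATF6bKO interferon-stimulated genes were shifted upward (3 of 23, median 0.514, adjusted p = 0.0175), and cell cycle genes were lower in 7 of 27 cases (median -0.421, adjusted p = 0.00615). With an estimated correlation these had adjusted p between 0.673 and 0.938. For ATF6aKO, the enteroendocrine call was lost without 1 array (WT titled DSS replicate 2 0.0633, titled UT replicate 1 0.106 and replicate 2 0.0728, ATF6aKO UT replicate 1 0.0539, ATF6aKO DSS replicate 2 0.054). So were the endothelial call (titled DSS replicate 2 0.0905, ATF6aKO DSS replicate 1 0.0525 and replicate 2 0.0521) and the ER-associated degradation call (titled DSS replicate 1 0.0729, titled UT replicate 2 0.0655, ATF6aKO UT replicate 1 0.0528, ATF6aKO DSS replicate 2 0.0521). For ATF6bKO this held for macrophage (titled DSS replicate 1 0.0776 and replicate 2 0.204, ATF6bKO DSS replicate 1 0.122 and replicate 2 0.141), interferon-stimulated (0.0903, 0.0624, 0.0918 and 0.0725 without the same arrays), endothelial (titled DSS replicate 2 0.0817, ATF6bKO DSS replicate 2 0.0725) and cell cycle genes (ATF6bKO DSS replicate 2 0.0725). With normexp the endothelial (0.194) and degradation (0.294) calls of ATF6aKO and the macrophage (0.394), interferon-stimulated (0.394) and endothelial (0.28) calls of ATF6bKO were lost. With quantile normalization the endothelial (0.0566) and degradation (0.0878) calls of ATF6aKO were lost, and with the strict filter its enteroendocrine (0.0702) and degradation (0.0505) calls. With the WT treatment read by the descriptions the endothelial and interferon-stimulated calls of ATF6bKO (0.112), its cell cycle call (0.31) and the endothelial call of ATF6aKO (0.09) were lost. The value table did not give the B cell, enteroendocrine and fatty acid oxidation calls of ATF6aKO (0.0652) or the macrophage (0.192) and interferon-stimulated (0.0848) calls of ATF6bKO. In the value table the medians of fatty acid oxidation (0.231) and enteroendocrine genes (0.183) in ATF6aKO and of cell cycle (0.227) and fatty acid oxidation genes (0.219) in ATF6bKO had the opposite sign.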

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

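Results were flagged here because they compare the DSS response between genotypes, rest on the conflicting WT labels, or follow slides. The regroupings of arrays had been planned before the data were examined, and the other tests in this part were chosen after the result was seen.

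The first pattern is that most genes called in the WT difference by the titles and in the pooled knockouts ran in 1 direction, although the macrophage, B cell, T and NK cell and translocon medians were opposite (-0.292, -0.678, -0.21 and -0.218 in WT). If WT responds like the knockouts, the 79.8% of genes called in both that went the same way argue against exchanged titles. That condition was not tested, so an exchange stays open. Descriptions written for the columns of the value table stay open as well. There 4 WT columns hold an array of the other WT group, which is the finding that prompted this explanation and cannot test it. RNA quality or tissue content that differs between the WT arrays remains open, because the arrays titled UT had the lowest correlation between replicates, 0.9722, and no value separates these sources.

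The second pattern is the downward shift of the interferon-stimulated list in the response of ATF6aKO minus that of ATF6bKO, with a median difference of -1.34 and 0 of 23 genes past the threshold. Squamous tissue in ATF6bKO DSS replicate 2 is an unlikely source, since the median difference without that array was -1.37, although replicate 1 carried a weaker squamous signal. Array scaling does not account for it either, as the value nearest to 0 under quantile normalization or normexp was -1.08. Differences between single animals may be the source: with an estimated correlation the list had adjusted p = 0.0627, which leaves it open. An effect of the missing ATF6 protein stays open as well and was not tested.

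The third pattern is that mast cell genes were higher in both knockouts than in WT, with list medians of 2.81 and 2.29. Slide and scan may be the source and cannot be told apart from genotype, because 0 slides hold over 1 genotype. Array scaling is an unlikely source: relative to the median of all genes the list was at 2.33 in ATF6bKO with quantile normalization and 2.34 with the values of the authors, against 2.31. With normexp, a background correction, it was at 1.25, so its size depended on the background, and the lowest median difference over the alternatives was 1.59. Genotype and housing of the mice stay open.

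Regrouping the 8 arrays of a fit gave few genes. The design could fit 34 splits, the real one included. The highest count of another split was 1 for the pooled DSS response and 0 for each knockout against WT. The real groups gave 6762 pooled, 8193 for ATF6aKO and 6827 for ATF6bKO. An arbitrary grouping is therefore unlikely as the source of these counts. Genotype splits are also slide splits, so slide alone could give their counts.

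The following are given as fitted values. For ATF6aKO minus WT the number of genes past the threshold was 1777 with WT by the titles and 6479 by the descriptions, and for ATF6bKO minus WT it was 3398 and 6799. Genes flagged for ATF6aKO minus WT by the titles were Olfr134 (5.22), Spaca1 (5.09), Wfdc21 (4.29), Epyc (4.22), Asic5 (3.88), Spag17 (-4.38), Cldn2 (-4.18), H2bc23 (-3.475), Tcf7l1 (-3.32) and Kif21b (-3.27). Genes flagged for ATF6bKO minus WT by the titles were Lce3f (9.07), Krtdap (8.275), Kprp (8.18), Krt1 (7.87), S100a8 (7.61), Prr18 (-6.31), Pgk2 (-5.44), Eml6 (-4.56), Nags (-4.52) and Syt6 (-4.41).

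List medians flagged for the response of ATF6aKO minus that of ATF6bKO were -0.0888 for goblet cell, -1.47 for neutrophil, -0.618 for macrophage, -1.35 for B cell, -1.43 for T and NK cell, 0.598 for smooth muscle, -0.426 for small intestine and pancreas, -0.338 for ER chaperones, -0.157 for ER-associated degradation, -0.172 for the translocon, -1 for acute inflammatory, -0.293 for antimicrobial, -1.34 for interferon-stimulated, 0.441 for cell cycle and -0.237 for fatty acid oxidation genes. For ATF6aKO minus WT by the titles they were -0.778 for crypt base, 0.592 for enteroendocrine, 1.24 for neutrophil, 1.32 for macrophage, 1.04 for B cell, 0.968 for T and NK cell, 0.76 for fibroblast and 0.387 for translocon genes. For ATF6bKO minus WT by the titles they were -0.709 for crypt base, 0.64 for enteroendocrine, 2.87 for neutrophil, 1.92 for macrophage, 2.41 for B cell, 2.4 for T and NK cell, 0.563 for fibroblast, 0.62 for ER chaperones, 0.537 for the translocon, 1.66 for inflammatory, 1.39 for antimicrobial and 1.75 for interferon-stimulated genes.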

How the results depend on the processing

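Of 352 called gene values, 44 lost their call with normexp, 14 with quantile normalization, 72 without a filter, 48 with the values of the authors (4 of them reversed, 336 tested), 19 with the mean of a gene's probes (1 reversed, and 1 more reversed and called), 76 with the replicate number as a block, 120 with only the arrays compared and 2 with the strict filter (235 tested in each), 7 of 46 with the WT treatment read by the descriptions and 6 of 110 without the WT arrays. Of 102 called list values, 12 lost it with normexp, 12 with quantile normalization, 8 with the strict filter, 1 without a filter, 9 in the value table, 4 with the mean of probes, 2 with a block, 4 of 15 with the WT treatment read by the descriptions and 3 of 69 with only the arrays compared. With 1 array left out in turn, 713 of 3756 gene values and 89 of 1092 list values lost their call, 0 and 2 of them reversed.

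With only its own 4 arrays the WT difference gave 635 genes, ATF6aKO 684 and ATF6bKO 1803, where fewer samples leave fewer degrees of freedom. Without the WT arrays ATF6aKO gave 2915 and ATF6bKO 4589; the cause was not tested, but the arrays titled UT had the widest spread between replicates (SD 0.69). Without a filter the counts were 694 for ATF6aKO, 260 for ATF6aKO minus WT by the titles and 1487 for ATF6bKO minus WT, and with the strict filter 2846 for ATF6aKO minus WT. Normexp gave 1796 for ATF6bKO and 12339 for ATF6bKO against WT. The value table gave 868 for ATF6aKO minus WT by the titles and 10647 for ATF6bKO against WT. For ATF6aKO minus ATF6bKO, quantile normalization gave 5 genes, the values of the authors 2 and only the arrays compared 4. With only the arrays compared ATF6aKO minus WT gave 158, ATF6bKO minus WT 890 by the titles and 4199 by the descriptions. The cause was not tested. Of 127 gene set shifts called by camera, 2 were left with an estimated correlation, against 119 to 129 gene set shifts with 1 array left out. What removed the others was not tested.

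Replicate numbers do not pair arrays: after removal of group means the replicates correlated across genes at 0.0106 for WT, 0.0746 for ATF6aKO and -0.0177 for ATF6bKO. As a block they gave 595 genes for ATF6aKO, 1936 for ATF6bKO, 0 for ATF6aKO minus WT and 1429 for ATF6bKO minus WT by the titles, and 3538 for ATF6bKO against WT.

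With 1 array left out the counts ran from 2970 to 10473 for WT, 183 to 3454 for ATF6aKO, 1093 to 5282 for ATF6bKO, 3856 to 6649 pooled and 0 to 83 for ATF6aKO minus ATF6bKO. They ran from 0 to 7620 and 735 to 8976 for ATF6aKO and ATF6bKO minus WT by the titles, 2951 to 10149 and 3958 to 10030 by the descriptions, 5391 to 8228 for ATF6aKO against WT and 4134 to 7043 for ATF6bKO against WT. The remaining array of a group was assumed to vary like the others.

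Processing moved the split of higher and lower genes. With normexp the share that was higher was 54.5% against 44.2% for ATF6bKO, 59% against 45.5% pooled, 61.5% against 41.6% for ATF6aKO against WT and 76.9% against 46.6% for ATF6bKO against WT, and for the last pair it was 87% and 90.1% in the value table. The median over all genes moved with normexp to 0.091 from -0.061 (ATF6bKO), 0.113 from -0.0107 (pooled), 0.147 from -0.00276 (ATF6bKO minus WT by the titles), 0.113 from 0.0124 and 0.106 from -0.0539 (ATF6aKO and ATF6bKO minus WT by the descriptions), 0.118 from -0.0732 (ATF6aKO against WT) and 0.339 from -0.0245 (ATF6bKO against WT). In the value table the last pair had 0.56 and 0.592, and without a filter ATF6bKO against WT had 0.105.

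Values that reversed were, in the value table, Fkbp11 (0.08335) and Sox9 (-0.20) in WT, Derl2 (-0.18) pooled and Eml6 (0.0373) for ATF6bKO minus WT, and with the mean of probes Bub1 (-0.61 in ATF6bKO, -0.66 pooled). List medians that reversed in the value table were enteroendocrine (0.183) and fatty acid oxidation (0.231) for ATF6aKO against WT, and cell cycle (0.227) and fatty acid oxidation (0.219) for ATF6bKO against WT, beside the shift of all genes there by 0.56 and 0.592. For ATF6aKO minus ATF6bKO the small intestine list had 0.0191 without a filter and 0.196 with the strict filter, the goblet list ran from -0.276 to 0.0362 with 1 array left out (0.0362 without ATF6bKO UT replicate 1), and the cell cycle list 0.149 without ATF6aKO DSS replicate 1, where the test turned. The cause was not tested.

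Signal over background limits the changes of dim genes: 66.0% to 76.9% of spots were well above it, and a gene below it in 1 group has only a bound.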

Other observations

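The mast cell list, written after the data had been seen, also changed with DSS: 10 of 14 measured genes rose and 1 fell over both knockouts (median 1.26, unadjusted camera p = 3.28e-05, 0.113 with an estimated correlation). In ATF6aKO 0 rose and 1 fell (median 1.14, unadjusted p = 0.00141, 0.104 with an estimated correlation), and in ATF6bKO 2 rose (median 1.21, unadjusted p = 0.000552, 0.0837 with an estimated correlation).

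On the WT arrays spike-in probes had 8.21 to 12.7 times the array's 75th percentile signal, and on the knockout arrays 373 to 625 times. The effect on genotype comparisons was not tested.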
